A study of Rattus norvegicus with 30 samples.

How the data were processed

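Livers of Wistar Han rats were profiled after exposure to DE-71, a technical mixture of polybrominated diphenyl ethers (PBDE), in corn oil. Per the labels' protocols, dams received 0 or 50 mg/kg by gavage at 5 ml/kg from gestation day 6 to postnatal day 21, on 7 days per week. Pups were also dosed directly until postnatal day 21, and dosing after weaning ran on 5 days per week. Livers were taken from pups on postnatal day 22 and from adult males at week 13. Each pup came from a different dam, and each adult came from a different dam within its dose group. Per the labels' protocols, RNA integrity was examined by gel electrophoresis, and 50 ng of total RNA entered a 2-cycle labelling from the 3' end. The labelled RNA was hybridised to Affymetrix Rat Genome 230 2.0 arrays.

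The deposited values are on a log2 scale, made by the authors with RMA per the labels; the RMA software and its version are not given in the sources used here. The table held 31099 probe sets on 30 arrays and 0 unused value columns. The 57 control probe sets were kept apart for quality measures, which left 31042 probe sets for testing. A platform table tied 20826 probe sets to 1 gene, 436 to several genes and 9780 to no gene. Gene symbols were brought up to date for 20758 probe sets. Each of 14217 genes was read from its representative, the probe set naming that gene alone with the highest mean over all arrays. Genes without such a probe set were not analysed here, among them Cyp2b1 and Cyp2b2.

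Groups were taken from the labels: 6 groups of 5 livers. The array names in the labels carry a prefix that divides the arrays into 2 batches of 3 groups each. The first batch held male control, female control and male PBDE pups. The second held female PBDE pups and both adult groups. Batch could not enter the model as a term because every group lay in 1 batch. Array numbers also ran in a consecutive block for each group, so an effect following them cannot be told apart from group. Replicate numbers in the titles do not name a shared dam, and the mean residual correlation of arrays with the same number was 0.00417 against -9.07e-04 for others, with 18 of 75 same-number pairs above 0.1. Of the 30 arrays, 11 were most like an array of their own number in another group, where chance gives about 6. A replicate block was an alternative.

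One linear model with a mean per group was fitted to all 30 arrays with limma 3.58.1 in R 4.3.3, with moderated statistics from eBayes and Benjamini-Hochberg adjustment over the 31042 probe sets. The 5 pairwise contrasts and the 2 interactions were those the series design names, where the authors' tool was R/maanova. Following that text, the false discovery rate was 0.01 for comparisons of pups and 0.05 for adults; age by dose was set at 0.05. Single values such as the difference between 3' and 5' control probe sets were compared by a two-sided exact permutation test over all regroupings of 5 against 5 arrays, whose smallest possible p is 0.00794. These p-values were adjusted over the 20 tests of that family.

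The comparisons, thresholds, gene lists, named-gene rule and most alternative settings were fixed before the data were examined. There were 34 gene lists holding 462 genes, of which 26 stand in more than 1 list. Lists of metabolism were AhR targets, CAR and PXR targets, NRF2 targets, glutathione transferases, glucuronosyl- and sulfotransferases, thyroid hormone handling and response, bile acid synthesis and transport, cholesterol synthesis, fatty acid and triglyceride synthesis, PPARalpha targets and fatty acid oxidation, gluconeogenesis and glucose metabolism, amino acid and urea metabolism, haem and iron, and the growth hormone and IGF axis. Lists of sex, age and stress were male-biased and female-biased adult liver genes, sex-chromosome genes, fetal and neonatal liver genes, cell cycle, p53 and DNA damage response, endoplasmic reticulum stress, acute phase response, interferon response and the circadian clock. Cell-type lists held markers of hepatocytes, Kupffer cells and macrophages, lymphocytes, neutrophils and myeloid progenitors, endothelium, stellate cells and fibroblasts, cholangiocytes, erythroid cells, exocrine pancreas and adipose tissue. Each list was tested with limma's camera on representative probe sets at a preset inter-gene correlation of 0.01, adjusted over the 34 lists within a contrast, at 0.05. An estimated correlation and limma's fry served as alternatives. Members were also counted after adjustment over the list alone.

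Genes were named by a fixed rule for each dose comparison. It took 22 index genes, of which 18 could be read, the 10 largest increases and the 10 largest decreases among genes past the threshold whose 5 PBDE arrays all lay on one side of the 5 controls, and up to 4 members with the largest changes in each list described. For the sex comparisons and interactions it took the sex-chromosome list, the 10 largest changes in each direction among genes past the threshold and up to 4 members of a list described. Probe-set counts include probe sets without a gene name.

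The analysis was tested on simulated data: 200 probe sets in a simulated null table were shifted by known amounts, 50 at each of 4 sizes. At a log2 change of 1 the fit recovered 96% of them for male pups, 94% for female pups, 96% for adults, 88% for sex by dose and 94% for age by dose. At a change of 0.5 it recovered 62%, 68%, 68%, 16% and 46%.

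Alternatives were a fit to the compared groups alone, a filter on probe sets at 6 or more on at least 5 arrays (15548 remained), centring of each array on its median, another quantile normalization, eBayes with trend and robust settings, no shrinkage of the spread, array weights, the replicate block, the other false discovery rate, a change of at least 1.5-fold, 1 representative per gene, removal of probe sets that can match several transcripts, the 15 arrays of 1 batch, and leaving out each array in turn. Chosen after seeing the data were the mean 3' minus 5' difference as a covariate and leaving out the 2 arrays least like their groups. Figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision of every value.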

Results

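Liver RNA was measured on 30 arrays from Wistar Han rats that received corn oil or DE-71, a mixture of polybrominated diphenyl ether (PBDE) flame retardants, at 50 mg/kg. There were 6 groups of 5 livers: male and female pups on postnatal day 22 and adult males at week 13, each as controls and as PBDE animals. Array medians ran from 5.72 to 5.77 on the log2 scale, and the mean correlation of an array with the rest of its group ran from 0.988 to 0.994. The first 3 principal components held 37.1%, 14.7% and 7.24% of the variance. Both groups lay in 1 array batch for the dose comparisons in male pups and in adults and for the sex comparison in controls. In female pups the PBDE arrays lay in the other batch than the controls. The difference between the 3' and 5' Gapdh control probe sets, a sign of RNA integrity, was 2.09 ± 0.65 (SD, n = 5) in male PBDE pups and 1.61 ± 0.33 in male control pups (exact permutation p = 0.198). It was 1.93 ± 0.30 against 1.26 ± 0.50 in female pups (exact p = 0.0397) and 1.17 ± 0.62 against 0.62 ± 0.18 in adults (exact p = 0.0238). After adjustment over 20 tests, those of Actb and of spike probe sets included, the lowest p was 0.198. Single arrays moved the Gapdh differences in both directions. Without adult PBDE rats replicate 5 the adult difference fell from 0.55 to 0.28 (exact p = 0.0476). Without male PBDE pups replicate 1 that in male pups fell from 0.48 to 0.27 (exact p = 0.389). The smallest unadjusted p of the 20 was that of hybridisation spikes in female pups (11.69 ± 0.11 with PBDE against 11.35 ± 0.15, exact p = 0.0159), whose groups lay in different batches.

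**Figure D1:**
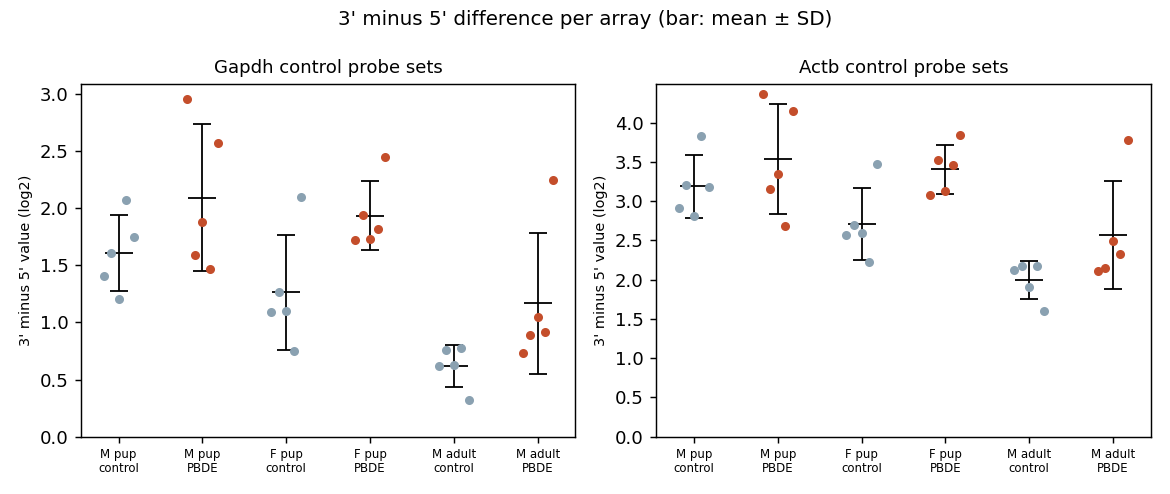
Difference between the 3' and 5' control probe sets of Gapdh and Actb (log2, vertical axis) on each array of the 6 groups; points are arrays and bars are mean ± SD, n = 5. For Gapdh the means were 2.09 in male PBDE pups, 1.93 in female PBDE pups and 1.17 in adult PBDE rats, against 1.61, 1.26 and 0.62 in their controls.

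The first comparison asked which liver transcripts differed between PBDE and control male pups. Cyp1a1, the classic target of the aryl hydrocarbon receptor, rose 26.7-fold (log2 4.74 ± 0.44 SE, n = 5 per group, adjusted p = 1.33e-08). Large increases were also seen for Rup2 (log2 7.81 ± 0.79), the cytochrome P450 Cyp2a3 (5.23 ± 0.50), the oestrogen sulfotransferase Sult1e1 (5.13 ± 0.35) and the amino acid transport partner Cltrn (4.82 ± 0.27). The other large increases were those of Cyp2c7 (4.57 ± 0.29), Cyp2c13 (4.40 ± 0.48), the chemokine Cxcl9 (3.41 ± 0.34), the sorting nexin Snx10 (3.33 ± 0.30) and the carboxylesterase Ces2c (3.17 ± 0.21). H19, an imprinted noncoding RNA abundant in fetal liver, had the largest decrease (log2 -3.74 ± 0.23, adjusted p = 3.53e-12). It was followed by the transcription factor Nfe2 (-3.05 ± 0.41), the protease inhibitor A2m (-2.65 ± 0.41), the sterol exporters Abcg8 (-2.63 ± 0.31) and Abcg5 (-2.19 ± 0.31), and the steroid hydroxylase Cyp17a1 (-2.62 ± 0.28). Fgf21 (-2.48 ± 0.37), Igfbp2 (-2.37 ± 0.31), Ppp2r2b (-2.27 ± 0.31) and Qpct (-2.19 ± 0.23) completed the 10 largest decreases. All these genes had 5 PBDE arrays on one side of 5 controls. In PBDE pups Cyp1a1 (mean 14.1) and Cyp2c7 (14.3) lay near the top of the scale, so their increases may be too small and have no exact rank. The control means of Rup2 (4.92, SD 2.13), Cyp2a3 (5.67), Cltrn (3.85), Cyp2c13 (4.81) and Snx10 (5.44) and the PBDE means of Abcg8 (4.87), Ppp2r2b (5.46) and Qpct (5.23) lay below the array medians, so these changes may also be too small and have no exact rank. Without male control pups replicate 3 the change of Rup2 was 8.67.

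Among the 18 index genes, further increases in male pups were those of Cyp2c11 (log2 2.80 ± 0.32), the quinone reductase Nqo1 (1.90 ± 0.26), the exporter Abcc3 (1.69 ± 0.25), Cyp1a2 (1.16 ± 0.18), the P450 reductase Por (1.13 ± 0.14) and Cyp3a23-3a1 (0.98 ± 0.09). Cyp1a2 (mean 14.6) and Cyp3a23-3a1 (14.6) lay near the top of the scale in PBDE pups, so their increases may be too small. Nr1i2, which encodes the pregnane X receptor, fell by 0.58 ± 0.09. The change did not pass the threshold for Ahr (1.11 ± 0.35, adjusted p = 0.0375), Nr1i3, which encodes the receptor CAR (-0.59 ± 0.19, adjusted p = 0.0424), Cdk1 (0.74 ± 0.24, adjusted p = 0.0404) or Cyp7a1, the first enzyme of bile acid synthesis (-1.20 ± 0.49, adjusted p = 0.123). Of these, 3 genes passed when the compared groups alone were fitted: Ahr at adjusted p = 0.00163 (range over alternatives 0.00163 to 0.103), Nr1i3 at 0.005 (0.005 to 0.0994) and Cdk1 at 0.00462 (0.00446 to 0.114). Gstp1, Dio1, Thrsp, Ttr and Cyp4a1 had adjusted p from 0.532 to 0.975, with log2 changes of -0.52 ± 0.45, -0.02 ± 0.23, -0.22 ± 0.20, -0.05 ± 0.04 and 0.11 ± 0.22. Ttr lay near the top of the scale in all 6 groups, so a change may have gone unmeasured.

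Xenobiotic-response lists rose in male pups. Of the CAR and PXR targets, 12 of 18 measured members rose, and 15 did when adjusted over the list alone (camera adjusted p = 3.1e-20, and 1.15e-04 with an estimated correlation). Cyp2c7, Ces2c and Gadd45b (log2 2.04 ± 0.20) led this list. Of the NRF2 targets, 9 of 16 rose, 10 when adjusted over the list alone, with Me1 (1.49 ± 0.20) and Gsta4 (1.29 ± 0.09) among them (adjusted p = 1.62e-09, and 0.0305 with an estimated correlation). Of the glucuronosyl- and sulfotransferases, 8 of 17 rose and 2 fell, 9 and 2 when adjusted over the list alone, with Sult1b1 (2.08 ± 0.17) second to Sult1e1 among those past the threshold (adjusted p = 6.86e-06, and 0.00554 with an estimated correlation). Of the AhR targets, 3 of 7 rose, 4 when adjusted over the list alone (adjusted p = 0.00128, and 0.0626 with an estimated correlation). Of the glutathione transferases, 8 of 19 rose, 10 when adjusted over the list alone, with Gstm2 at 1.41 ± 0.25 (adjusted p = 2.31e-05, and 0.175 with an estimated correlation). Cyp1b1, an AhR target, stood at 2.31 ± 0.60 (adjusted p = 0.0104) and passed without male PBDE pups replicate 1 (2.93, adjusted p = 5.61e-04) or replicate 2 (2.75, adjusted p = 0.00276), and stood at 1.54 without replicate 3 (adjusted p = 0.0377; range 5.61e-04 to 0.0941).

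In male pups the cholesterol, amino acid, gluconeogenesis and fatty acid lists passed in the lower direction, and of these the gluconeogenesis list alone held with an estimated correlation. Of 18 measured cholesterol synthesis genes, 9 fell, 13 when adjusted over the list alone, led by Hsd17b7 (log2 -1.48 ± 0.23) and Idi1 (-1.41 ± 0.26); the list's adjusted p was 6.14e-11, and 0.17 with an estimated correlation. Of 20 amino acid and urea genes, 6 fell, 7 when adjusted over the list alone, with Agxt at -1.06 ± 0.14 (adjusted p = 2.99e-06, and 0.0897 with an estimated correlation). Of 13 gluconeogenesis and glucose genes, 4 fell, 5 when adjusted over the list alone, with Fbp1 at -0.52 ± 0.09 (adjusted p = 1.02e-04, and 0.0305 with an estimated correlation). Among 19 fatty acid and triglyceride genes, 2 rose, Me1 among them, and 4 fell, with Fads2 at -1.57 ± 0.19; adjusted over the list alone, 2 rose and 5 fell (list adjusted p = 0.0319, and 0.574 with an estimated correlation). Cell cycle genes rose as a list, with 6 of 28 members higher, among them Ccnb1 (0.96 ± 0.19), and Ccnd1 lower (-1.22 ± 0.30). Adjusted over the list alone, 14 rose and 1 fell (list adjusted p = 3.85e-07, and 0.217 with an estimated correlation). The Ccnd1 call (adjusted p = 0.00651) was lost without any 1 of male control pups replicates 2, 4 and 5 or male PBDE pups replicates 2, 3 and 5, at adjusted p from 0.0131 to 0.0281. Its adjusted p was 0.0122 with a replicate block 0.0116 with a trended, robust eBayes and 0.0155 with no shrinkage, within a range of 0.0028 to 0.0281 over its alternatives.

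Both lists of sex-biased adult genes rose in male pups. Of 11 male-biased genes, 5 rose, 6 when adjusted over the list alone, with Sult1e1, Cyp2c13 and Cyp2c11 leading (adjusted p = 1.9e-05, and 0.0305 with an estimated correlation). Of 9 female-biased genes, 2 rose, Cyp2c7 among them, and 1 fell; adjusted over the list alone, 3 rose and 1 fell (adjusted p = 0.00728, and 0.0305 with an estimated correlation). Endothelial markers fell, 4 of 12 in number and 7 when adjusted over the list alone, with Fcgr2b at log2 -0.89 ± 0.12 and Stab2 at -0.79 ± 0.13 (adjusted p = 2.58e-05, and 0.0626 with an estimated correlation). Kupffer cell and macrophage markers fell, 2 of 12 and 3 when adjusted over the list alone, namely Aif1 (-0.77 ± 0.17) and C1qa (-0.71 ± 0.17) over all probe sets (list adjusted p = 0.00326, and 0.493 with an estimated correlation). The C1qa call (adjusted p = 0.0058) was lost without any 1 of male control pups replicates 1, 2, 4 and 5 or male PBDE pups replicates 2 to 5 (adjusted p 0.0102 to 0.0173), with no shrinkage of the spread (0.0125) and with the 3' minus 5' covariate (0.0142), within a range of 2.88e-04 to 0.0173. Interferon response genes had 1 riser among 17, 2 when adjusted over the list alone (adjusted p = 0.0319, and 0.605 with an estimated correlation). That call was lost without male control pups replicate 3 (0.181) or 4 (0.168) or male PBDE pups replicate 1 (0.052) or 4 (0.0512). The fatty acid and triglyceride call was lost without male control pups replicate 2 (0.0979) or male PBDE pups replicate 4 (0.0594) and with the filter on low values (0.0639). With fry, which tests a list without its background, the adjusted p was 0.135 for fatty acid genes, 0.131 for interferon genes and 0.089 for Kupffer cell markers.

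The other 19 lists did not pass in male pups, with adjusted p from 0.0733 to 0.921. They were fetal and neonatal genes, hepatocyte, lymphocyte, neutrophil, erythroid, adipose, cholangiocyte, stellate cell and exocrine pancreas markers, thyroid hormone handling, p53 and DNA damage, sex-chromosome genes, bile acid synthesis and transport, PPARalpha targets, acute phase, endoplasmic reticulum stress, circadian clock, the growth hormone axis, and haem and iron. For the clock and the growth hormone axis, median, mean and test differed in sign. The fetal and neonatal list passed without male control pups replicate 2 (0.0456) or 3 (0.0473) or male PBDE pups replicate 2 (0.046). In the thyroid list 1 of 17 members rose, Me1, and 1 fell, the thyroxine carrier Serpina7 (log2 -2.18 ± 0.39). In the bile acid list 2 of 17 rose, Abcc3 and the exporter Abcc2 (1.69 ± 0.15), and 4 fell, with the enzyme Cyp8b1 lowest (-1.55 ± 0.31). The numbers were the same when adjusted over each list alone.

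In all, 1654 of 31042 probe sets passed the false discovery rate of 0.01 in male pups, 897 higher and 757 lower in PBDE, and 902 higher and 904 lower with the 3' minus 5' covariate. By representative probe set, 601 genes rose and 463 fell, and 925 of these 1064 genes, chosen on the same arrays, did not overlap between the groups. Of all 14217 genes, 1693 did not overlap, where chance gives 0.794%. A change of at least 2-fold was seen for 248 probe sets.

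**Figure D2:**
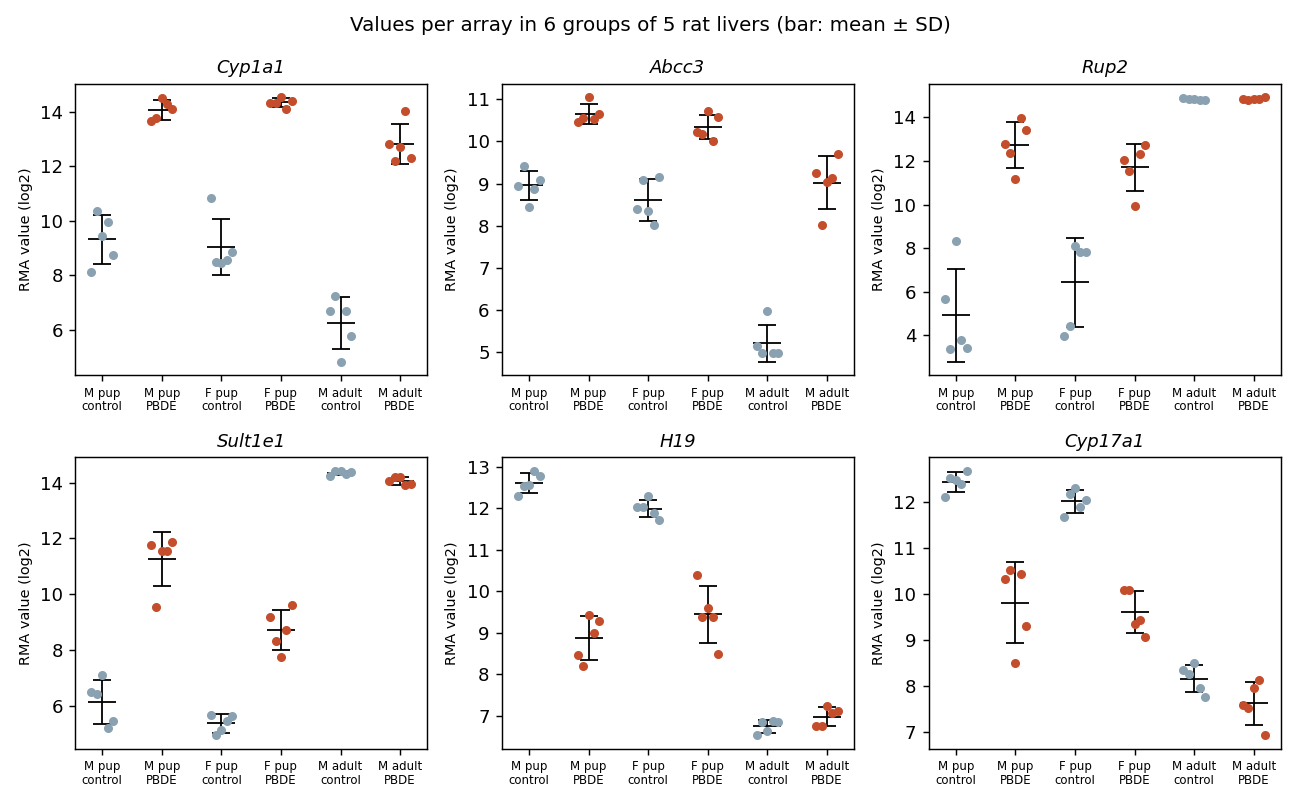
RMA values (log2, vertical axis) of 6 genes on each array of the 6 groups; points are arrays and bars are mean ± SD, n = 5. Cyp1a1 averaged 14.1 in male PBDE pups against 9.32 in their controls, and 12.8 in adult PBDE rats against 6.24 in theirs.

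The second comparison asked the same of female pups, whose groups lay in different array batches. Over the 1315 probe sets called in females, the log2 change in male pups, measured within 1 batch, was a median of 0.855 of the female change (quartiles 0.645 and 1.06). Cyp1a1 rose 39.6-fold (log2 5.31 ± 0.44, n = 5 per group, adjusted p = 1.51e-09), which may be too small because its mean in PBDE pups (14.3) lay near the top of the scale, as did that of Cyp2c7 (14.4). Rup2 (5.28 ± 0.79), Cltrn (4.94 ± 0.27), Ttc39a (3.89 ± 0.22), Cyp1b1 (3.45 ± 0.60) and Snx10 (3.45 ± 0.30) followed. Sult1e1 (3.34 ± 0.35), Cyp2c7 (3.20 ± 0.29), Cxcl9 (3.08 ± 0.34) and the palmitoyltransferase Zdhhc2 (2.97 ± 0.15) were also among the 10 largest increases. The largest decreases were those of the taurine transporter Slc6a6 (-2.84 ± 0.28), A2m (-2.83 ± 0.41), Ppp2r2b (-2.66 ± 0.31), Nfe2 (-2.66 ± 0.41) and H19 (-2.54 ± 0.23). Cyp17a1 (-2.41 ± 0.28), Hsd17b6 (-2.32 ± 0.34), Fgl1 (-2.24 ± 0.40), Edil3 (-2.24 ± 0.35) and Abcg8 (-2.23 ± 0.31) followed. The control means of Cltrn (4.09), Ttc39a (3.92), Cyp1b1 (5.31), Snx10 (5.41) and Sult1e1 (5.38) and the PBDE means of Ppp2r2b (5.62), Edil3 (5.04) and Abcg8 (4.68) lay below the array medians, so these changes may be too small and have no exact rank. Without female control pups replicate 4 the change of A2m was -2.24, and without replicate 1 that of Rup2 was 4.67. The Fgl1 call (adjusted p = 4.42e-04) was lost when the compared groups alone were fitted (0.0276; range 8.24e-05 to 0.0276).

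Of the index genes, Abcc3 (log2 1.73 ± 0.25), Por (1.31 ± 0.14), Cyp2c11 (1.29 ± 0.32), Nqo1 (1.18 ± 0.26), Cyp1a2 (1.09 ± 0.18) and Cyp3a23-3a1 (1.02 ± 0.09) also rose in female pups. The increases of Cyp1a2 and Cyp3a23-3a1 may be too small, with means of 14.8 and 14.6 in PBDE pups near the top of the scale. Nr1i2 fell by 0.46 ± 0.09 and Nr1i3 by 0.76 ± 0.19. The Nqo1 call (adjusted p = 0.00315) was lost without female control pups replicate 4 (0.0122) or female PBDE pups replicate 1 (0.0135) or 5 (0.0126), and with the 3' minus 5' covariate (0.015; range 4.67e-04 to 0.015). The Cyp2c11 call (adjusted p = 0.00942) was lost without female control pups replicate 1, 2 or 3 or female PBDE pups replicate 2, 3, 4 or 5 (0.0128 to 0.0393). It was also lost with the compared groups alone (0.0107), a replicate block (0.0125), a trended, robust eBayes (0.0176), no shrinkage (0.0217), the covariate (0.0417) and without the 2 arrays least like their groups (0.0121), and its range was 0.00464 to 0.0417. The Nr1i3 call (adjusted p = 0.00932) was lost without female control pups replicate 2, 3 or 5 or any 1 of the 5 female PBDE pups (0.012 to 0.0398). It was lost as well with a replicate block (0.0175), the compared groups alone (0.0189), renewed quantile normalization (0.0105), a trended, robust eBayes (0.0105), no shrinkage (0.0197) and the covariate (0.0209), with a range of 0.00175 to 0.0398. Cdk1 (0.87 ± 0.24, adjusted p = 0.0181) passed without female PBDE pups replicate 1 (0.00332; range 0.00332 to 0.0759). Gstp1, Dio1, Thrsp, Ttr, Cyp7a1, Cyp4a1 and Ahr had adjusted p from 0.216 to 0.911, with log2 changes of 0.55 ± 0.45, 0.08 ± 0.23, 0.13 ± 0.20, -0.02 ± 0.04, -1.06 ± 0.49, 0.32 ± 0.22 and 0.30 ± 0.35.

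In female pups 5 lists held at both correlations. CAR and PXR targets rose in 11 of 18 members; adjusted over the list alone, 12 rose and 1 fell (adjusted p = 1.57e-16, and 4.87e-04 with an estimated correlation). Ces2c stood at log2 2.22 ± 0.21 in this list. AhR targets rose in 5 of 7 members, also when adjusted over the list alone (adjusted p = 1.81e-07, and 0.00663 with an estimated correlation). NRF2 targets rose in 8 of 16 members, 11 when adjusted over the list alone, with Me1 at 1.68 ± 0.20 (adjusted p = 6.41e-11, and 0.0162 with an estimated correlation). Glucuronosyl- and sulfotransferases rose in 6 of 17 members and fell in 1, with 8 and 1 when adjusted over the list alone (adjusted p = 8.12e-05, and 0.0109 with an estimated correlation). Amino acid and urea genes fell in 8 of 20 members, 15 when adjusted over the list alone, with the glutaminase Gls2 (-1.21 ± 0.18), the methyltransferase Gnmt (-1.20 ± 0.18) and Agxt (-1.19 ± 0.14) leading those past the threshold (adjusted p = 3.27e-13, and 0.0109 with an estimated correlation).

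The other 11 lists past the threshold in female pups were lost with an estimated correlation. Cholesterol synthesis genes fell, 4 of 18 and 9 when adjusted over the list alone, with Hsd17b7 at log2 -1.36 ± 0.23 (adjusted p = 9.59e-10, and 0.189 with an estimated correlation). Cell cycle genes rose, 4 of 28; adjusted over the list alone, 11 rose and 1 fell (adjusted p = 4.43e-08, and 0.189 with an estimated correlation). Glutathione transferases rose, 7 of 19 and 9 when adjusted over the list alone, with Gsta4 at 1.18 ± 0.09 (adjusted p = 4.64e-05, and 0.189 with an estimated correlation). Interferon response genes rose, 4 of 17 and 5 when adjusted over the list alone, with Oas1a at 1.53 ± 0.29 (adjusted p = 5.86e-05, and 0.216 with an estimated correlation). Acute phase genes fell, 2 of 17 and 8 when adjusted over the list alone (adjusted p = 1.61e-05, and 0.189 with an estimated correlation). Gluconeogenesis and glucose genes fell, 2 of 13 and 4 when adjusted over the list alone (adjusted p = 0.00115, and 0.0849 with an estimated correlation). Endothelial markers fell, 2 of 12 by either count, with Fcgr2b at -0.63 ± 0.12 (adjusted p = 0.00558, and 0.189 with an estimated correlation); with the filter on low values the adjusted p was 0.0509. Erythroid markers rose as a list at adjusted p = 0.00171, and stood at 0.209 with an estimated correlation and 0.0829 with fry's mixed test; 4 of 10 members passed only when adjusted over the list alone, and Slc4a1 (0.83 ± 0.28, adjusted p = 0.0598) and Ahsp (0.81 ± 0.22, adjusted p = 0.0178) stood highest. Ahsp passed when the compared groups alone were fitted (5.34e-04; range 5.34e-04 to 0.0439).

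Lists on thyroid hormone (adjusted p = 0.0394), hepatocyte markers (0.0394) and bile acids (0.0453) passed in the lower direction in female pups and stood at 0.189, 0.107 and 0.189 as adjusted p with an estimated correlation. Without 1 array, the thyroid list was lost for female control pups replicates 2 and 5 and PBDE replicate 5 (0.0687 to 0.0927). The hepatocyte list was lost for control replicates 4 and 5 and PBDE replicates 4 and 5 (0.0514 to 0.0704), and the bile acid list for control replicates 2 and 5 and PBDE replicates 2, 4 and 5 (0.0514 to 0.0983). All 3 were lost with the filter on low values (0.0697, 0.0674 and 0.0674), and the hepatocyte list also with the mean of each gene's probe sets (0.076). In the thyroid list 1 of 17 members rose, Me1, and 1 fell, Serpina7 (log2 -2.15 ± 0.39); adjusted over the list alone, 1 rose and 3 fell. In the bile acid list 2 of 17 rose, Abcc3 and Abcc2 (1.21 ± 0.15), and 3 fell by either count, with Cyp8b1 lowest (-2.07 ± 0.31). The remaining 18 lists had adjusted p from 0.0573 to 0.887, namely sex-chromosome, male-biased, female-biased, fetal, p53, fatty acid synthesis, PPARalpha, growth hormone, clock, endoplasmic reticulum stress and haem lists and the Kupffer cell, lymphocyte, pancreas, neutrophil, adipose, cholangiocyte and stellate cell markers. Of these, the sex-chromosome list passed without female control pups replicate 1 (0.0119) or PBDE replicate 2 (0.0491) or 3 (0.0165), and the Kupffer cell list without control replicate 2 (0.00323) or 5 (0.0429). Median, mean and test differed in sign for the fetal, haem, endoplasmic reticulum stress, stellate cell and cholangiocyte lists.

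The count past the false discovery rate of 0.01 in female pups was 1315 probe sets, 792 higher and 523 lower. These gave 562 genes that rose and 310 that fell, and 769 of the 872 had arrays apart. Of all 14217 genes, 1555 had arrays apart, where chance gives 0.794%. At least 2-fold changes were seen for 207 probe sets.

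Male and female pups were compared across all probe sets, which are not independent replicates. The log2 changes correlated at Pearson's r = 0.753 and Spearman's rho = 0.591. Of the probe sets higher in PBDE male pups, 522 were also called higher in females, where independence would give 22.9. Of those lower, 268 were shared against 12.8. The sign in females was that in males for 98.8% of the 897 increases and 97.9% of the 757 decreases.

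**Figure D3:**
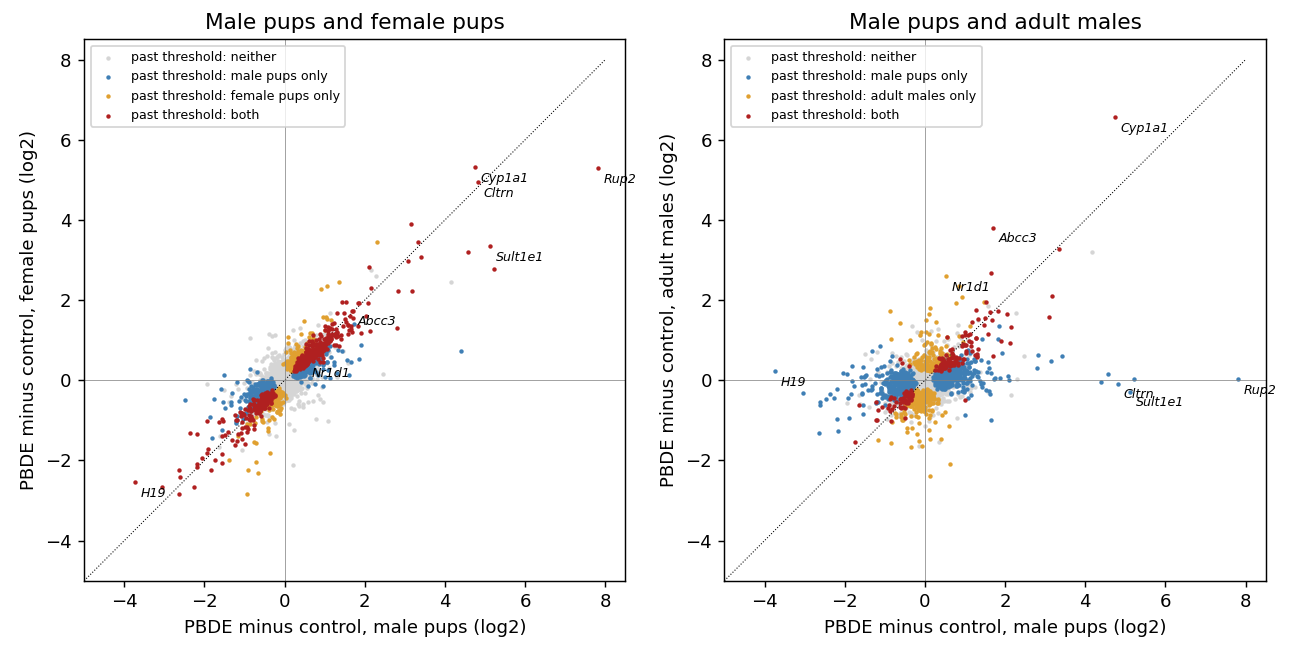
Log2 change with PBDE of each gene's representative probe set in male pups (horizontal axis) against female pups (left) and adult males (right); colours mark genes past the threshold in 1 or both comparisons and the dotted line marks equal changes. Cyp1a1 lay at 4.74, 5.31 and 6.56 in male pups, female pups and adults, and Rup2 at 7.81, 5.28 and 0.02.

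In adult males at week 13, the question was which genes differed after dosing through adulthood. Cyp1a1 rose 94.4-fold (log2 6.56 ± 0.44, n = 5 per group, adjusted p = 3.05e-11), from a mean of 6.24 ± 0.95 (SD) in controls to 12.8 ± 0.73. Abcc3 rose by log2 3.81 ± 0.25 (SE; adjusted p = 3.05e-11). Further large increases were those of Snx10 (3.27 ± 0.30), the protease Prss8 (2.66 ± 0.25), the clock repressor Nr1d1 (6.04-fold, SE 0.39 on the log2 scale), the glutathione transferase Gsta3 (2.36 ± 0.33) and Ces2c (2.09 ± 0.21). Sema3c (1.96 ± 0.40), Nipal2 (1.95 ± 0.18) and Tmem30b (1.92 ± 0.23) completed the list. The largest decreases were those of Fbxl17l1 (-2.40 ± 0.22), the cytokine-signalling suppressor Socs2 (-2.09 ± 0.35), the kinase Nim1k (-1.66 ± 0.28), the homeobox gene Hhex (-1.64 ± 0.26) and the phosphatase Dusp1 (-1.57 ± 0.33). Ccdc126 (-1.33 ± 0.16), the cell cycle inhibitor Cdkn1a (-1.29 ± 0.22), Lurap1l (-1.24 ± 0.29), Zfp189 (-1.20 ± 0.23) and Cyp2c12 (-1.13 ± 0.17) followed. The control means of Abcc3 (5.22), Snx10 (4.59), Prss8 (5.68), Nr1d1 (5.12) and Sema3c (4.52) and the PBDE mean of Fbxl17l1 (4.87) lay below the array medians, so these changes may be too small and have no exact rank. Without adult male PBDE rats replicate 4 the Lurap1l call (adjusted p = 0.0123) was lost at 0.0535, within a range of 0.00766 to 0.0535.

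Index genes that also rose in adults were Por (log2 1.15 ± 0.14), Nqo1 (0.97 ± 0.26), Cyp1a2 (0.94 ± 0.18) and Cyp3a23-3a1 (0.54 ± 0.09), of which Cyp1a2 and Cyp3a23-3a1 averaged 14.3 and 14.5 in PBDE rats, near the top of the scale, and may have risen more. The Nqo1 call (adjusted p = 0.0346) was lost without adult male controls replicate 1, 3 or 5 or adult PBDE rats replicate 1, 3, 4 or 5 (0.0504 to 0.124). It was also lost with the compared groups alone (0.202), the 15 arrays of the batch (0.111), the 3' minus 5' covariate (0.0836) a trended, robust eBayes (0.0528) and no shrinkage (0.0643), and its range was 0.00172 to 0.202. The Cyp1a2 call (adjusted p = 0.00204) was lost with the compared groups alone (0.103; range 4.25e-04 to 0.103). Gstp1, Dio1, Thrsp, Ttr, Cyp7a1, Cyp4a1, Cyp2c11, Cyp17a1, Cdk1, Ahr, Nr1i2 and Nr1i3 did not pass, with adjusted p from 0.201 to 0.907. Their log2 changes were -0.45 ± 0.45, -0.41 ± 0.23, 0.49 ± 0.20, -0.04 ± 0.04, 0.71 ± 0.49, -0.15 ± 0.22, 0.30 ± 0.32, -0.54 ± 0.28, 0.08 ± 0.24, 0.64 ± 0.35, -0.03 ± 0.09 and -0.15 ± 0.19. The change of Cyp7a1 was 0.26 without adult PBDE rats replicate 4 and 1.19 without replicate 1, and that of Ahr was 0.99 without replicate 2. Thrsp passed at 0.05 without adult PBDE rats replicate 3 (range 0.05 to 0.687).

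CAR and PXR targets rose in adults, 12 of 18 members and 13 when adjusted over the list alone, among them Ugt2b1 (log2 1.75 ± 0.12), Gadd45b (1.66 ± 0.20) and the epoxide hydrolase Ephx1 (0.77 ± 0.13). This list's adjusted p was 3.27e-21, and 8.09e-05 with an estimated correlation. The other 8 lists past the threshold were lost with an estimated correlation. AhR targets rose, 3 of 7; adjusted over the list alone, 3 rose and 1 fell (adjusted p = 0.00186, and 0.137 with an estimated correlation). NRF2 targets rose, 4 of 16 and 6 when adjusted over the list alone, with Me1 at 1.38 ± 0.20 and Gsta4 at 0.59 ± 0.09 (adjusted p = 0.00186, and 0.416 with an estimated correlation). Fatty acid and triglyceride genes rose, 3 of 19, with the elongase Elovl6 (1.43 ± 0.33) and the carboxylase Acaca (0.91 ± 0.20) beside Me1; adjusted over the list alone, 8 rose and 1 fell (list adjusted p = 0.00186, and 0.445 with an estimated correlation). Without the 2 arrays least like their groups, Elovl6 stood at adjusted p = 0.0761 (range 0.00768 to 0.0761) and Acaca at 0.118 (0.00589 to 0.118). The list stood at 0.0514 with fry, and with the 3' minus 5' covariate Elovl6 stood at 0.0505. Glucuronosyl- and sulfotransferases rose, 2 of 17; adjusted over the list alone, 5 rose and 1 fell (adjusted p = 0.00939, and 0.137 with an estimated correlation).

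Kupffer cell and macrophage markers fell in adults, 1 of 12 and 8 when adjusted over the list alone (adjusted p = 1.4e-05, and 0.416 with an estimated correlation; 0.211 with fry's mixed test). The member past the threshold was Aif1 (log2 -0.64 ± 0.17, adjusted p = 0.0323), and C1qb stood at -0.68 ± 0.23 (adjusted p = 0.104). The Aif1 call was lost without adult male controls replicate 2 or 4 or adult PBDE rats replicate 2, 4 or 5 (0.0666 to 0.11). It was also lost with the compared groups alone (0.155), the 15 arrays of the batch (0.0811), no shrinkage (0.0571), array weights (0.0556), the 3' minus 5' covariate (0.116) and without the 2 arrays least like their groups (-0.38, adjusted p = 0.348), over a range of 0.00527 to 0.348. Glutathione transferases rose, 4 of 19, with Gstm3 at 1.14 ± 0.19; adjusted over the list alone, 8 rose and 1 fell (adjusted p = 0.0351, and 0.65 with an estimated correlation). Amino acid and urea genes passed in the lower direction at 0.0351 (adjusted p = 0.591 with an estimated correlation), although by either count 1 of 20 rose, Asns (1.73 ± 0.41), and 1 fell, the glutamine synthetase Glul (-0.95 ± 0.12). The Asns call was lost without adult PBDE rats replicate 4 (0.0535; range 1.88e-05 to 0.0535). The p53 and DNA damage genes fell, 2 of 11, namely Cdkn1a and Aen (-0.64 ± 0.13); adjusted over the list alone, 1 rose and 5 fell (list adjusted p = 0.0351, and 0.445 with an estimated correlation). Without 1 array, the glutathione list was lost for adult controls replicate 1 (0.0838) and PBDE replicate 1 (0.172). The amino acid list was lost for controls replicates 1 and 5 and PBDE replicates 1, 3 and 5 (0.0591 to 0.282), and the p53 list for controls replicates 1 and 4 and PBDE replicates 1 and 4 (0.0616 to 0.275). With the filter on low values, the amino acid and p53 lists both stood at 0.139. With fry the adjusted p was 0.135 for glutathione transferases, 0.215 for amino acid genes and 0.0514 for p53 genes.

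The circadian clock list did not pass in adults (adjusted p = 0.88), and its median and its test differed in sign; 2 of 16 members rose and 2 fell, or 5 and 4 adjusted over the list alone. Beside Nr1d1, Nr1d2 rose by log2 1.46 ± 0.30 and the repressor Cry1 fell by 1.18 ± 0.22, while Dbp stood at 1.37 ± 0.54 (adjusted p = 0.18), and at 0.63 without adult PBDE rats replicate 5 (adjusted p = 0.524; range 0.0765 to 0.524). With the compared groups alone, Nr1d2 (adjusted p = 0.134; range 5.78e-04 to 0.134) and Cry1 (0.0583; range 1.67e-04 to 0.0583) were lost. Over adult PBDE rats Nr1d1 ran from 6.19 to 9.40 and Dbp from 5.52 to 9.95, and both were higher on replicates 3 to 5 than on 1 and 2. For Dbp, replicate 3 (5.85) lay close to replicate 2 (5.79). Replicates 3 to 5 lay together in the other split of the adult arrays given below. Control replicates 1 and 5, on the same side of that split, did not stand above the other controls. Nr1d1 was 4.41 and 5.70 on them against 4.69 to 5.94 on the others, and Dbp 5.89 and 5.08 against 5.38 to 5.90. Sampling time was not tested as a cause. Among cholangiocyte markers (adjusted p = 0.176), Epcam rose by 1.13 ± 0.18. In the growth hormone list (adjusted p = 0.0653), which passed without adult controls replicate 2 (0.047) or PBDE replicate 3 (0.0347), Cish stood at -1.55 ± 0.50 (adjusted p = 0.0899), and passed without adult controls replicate 5 (0.0426; range 0.0426 to 0.313). The other 22 lists had adjusted p from 0.165 to 0.897: hepatocyte, neutrophil, lymphocyte, adipose, stellate cell, endothelial, pancreas and erythroid markers, bile acids, interferon, thyroid hormone, cholesterol, acute phase, PPARalpha, gluconeogenesis, endoplasmic reticulum stress, cell cycle, haem, male-biased, female-biased, sex-chromosome and fetal lists. Of these, the interferon list passed without adult controls replicate 3 (0.00561). Median, mean and test differed in sign for the PPARalpha, haem, sex-chromosome, fetal, endoplasmic reticulum stress, acute phase, stellate cell and erythroid lists.

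At the false discovery rate of 0.05, 924 probe sets passed in adults, 414 higher and 510 lower. The balance turned with the scaling of the arrays: 516 were higher and 454 lower with renewed quantile normalization, and 349 and 576 with arrays centred on their medians. It was 144 and 125 with the compared groups alone. By gene 265 rose and 290 fell, 335 of the 555 had arrays apart, and 111 probe sets changed at least 2-fold. Of all 14217 genes, 652 had arrays apart, where chance gives 0.794%. Without adult PBDE rats replicate 4 the count was 597. It was 269 with the compared groups alone, 535 with the 15 arrays of the batch and 494 without the 2 arrays least like their groups. The main fit shares 1 spread per probe set with the pup groups, whose arrays were more alike. Adult p-values from it may therefore be too small. Another split of the same 10 arrays, control replicates 1 and 5 with PBDE replicates 3, 4 and 5 against the others, gave 1355 probe sets, more than dose did.

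**Figure D4:**
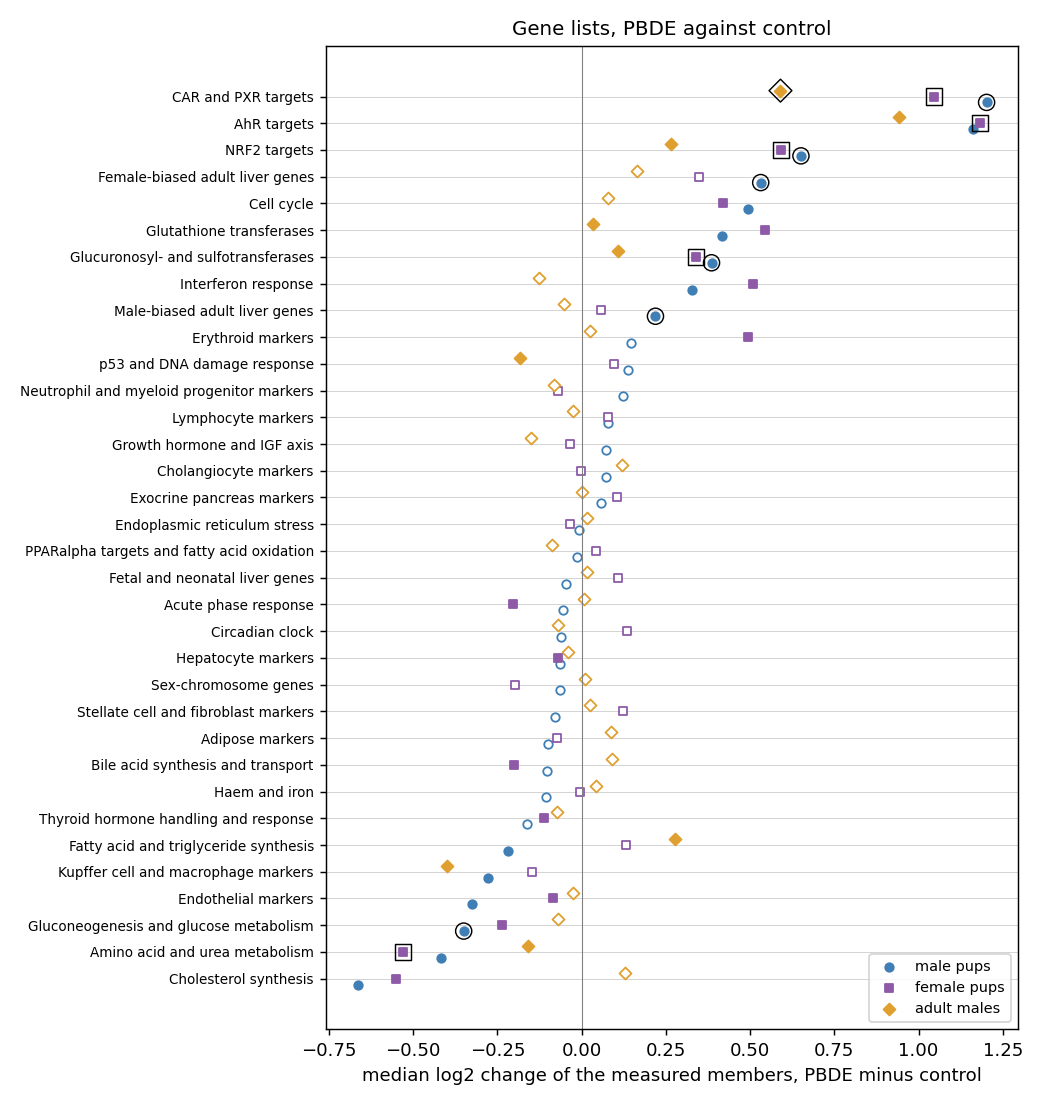
Median log2 change with PBDE over the measured members of each of the 34 gene lists (horizontal axis) in male pups, female pups and adult males; filled symbols mark an adjusted p at or under 0.05 at the preset correlation, and a black outline marks lists that also held with an estimated correlation. The CAR and PXR medians were 1.20, 1.04 and 0.59.

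Across probe sets, which are not independent replicates, the changes in male pups and in adults correlated at Pearson's r = 0.354 and Spearman's rho = 0.267. They shared 156 increases against 11.96 under independence and 83 decreases against 12.4, and 7 probe sets were called in opposite directions, 3 of them higher in pups. The adult change had the pup's sign for 80.8% of the pup increases and 77.1% of the decreases. Female pups and adults correlated at r = 0.386, and shared 143 increases against 10.6 and 82 decreases against 8.59.

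The age-by-dose test asked directly whether the male dose effect differed between week 13 and postnatal day 22, with values given as adult minus pup effect. Effects are signed, so a higher adult effect can be a weaker fall than in pups, or none, as for H19 and Cyp17a1. Age and length of dosing cannot be told apart. Rup2 stood at log2 -7.79 ± 1.11 (adjusted p = 1.67e-04), or -8.65 without male control pups replicate 3, and averaged 14.8 in adult controls and 14.9 in adult PBDE rats, against 4.92 and 12.7 in pups. Sult1e1 (-5.41 ± 0.50), Cyp2c13 (-4.45 ± 0.67) and Cyp2c7 (-4.40 ± 0.41) were likewise high in both adult groups, with means of 14.04 to 14.49. These 4 genes lay near the top of the scale in adults, so a further adult rise may have gone unmeasured. Their differences by age may then be too large. The pup rises of Rup2, Cyp2c13 and Cyp2c7 may be too small as given above, which would act the other way. The direction of the bias is therefore open for them. Cyp2a3 (-5.19 ± 0.71) and Cltrn (-4.91 ± 0.38) were low in both adult groups, at 3.59 to 4.41. These lay below the array medians, where an adult change may go unmeasured, so both differences have no exact size or rank. Cxcl9 (-2.80 ± 0.48), Socs2 (-2.70 ± 0.49), Ttc39a (-2.66 ± 0.31) and the hydroxyacid oxidase Hao2 (-2.64 ± 0.50) followed. The male control pup means of Cltrn (3.85) and Hao2 (5.21) also lay below the array medians, so their pup rises may be too small. Differences towards a higher adult effect were seen for H19 (3.97 ± 0.32), Nfe2 (2.72 ± 0.58), Asns (2.59 ± 0.58), Qsox1 (2.23 ± 0.26) and Aacs (2.16 ± 0.51). Noct (2.16 ± 0.56), Abcc3 (2.11 ± 0.35), G0s2 (2.11 ± 0.33), Cyp17a1 (2.08 ± 0.40) and Nr1d1 (2.06 ± 0.55) followed. Adult control means of Nfe2, Asns, Noct, Abcc3 and Nr1d1 (5.12 to 5.43) lay below the array medians, where an adult fall may go unmeasured and a rise may be too small, so these 5 differences have no exact size or rank. Cyp1a1 did not pass (1.82 ± 0.62, adjusted p = 0.136), and this value may be too large because its mean of 14.1 in PBDE pups lay near the top of the scale. Xist (0.05 ± 0.22) and Eif2s3y (0.16 ± 0.14) did not pass.

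Among the differences by age, the Aacs call (adjusted p = 0.0227) was lost without adult PBDE rats replicate 4 (0.0518), without the 2 arrays least like their groups (0.0509) and with no shrinkage (0.0507; range 0.00606 to 0.0518). The Noct call (adjusted p = 0.0391) was lost without male control pups replicate 2, 3 or 5, male PBDE pups replicate 2, 3, 4 or 5, any 1 of adult controls replicates 1 to 4 or adult PBDE rats replicate 2, 4 or 5 (0.0518 to 0.0829). It was lost as well with a trended, robust eBayes (0.0625), with no shrinkage (0.0743) and without the 2 arrays least like their groups (0.119), within a range of 0.0155 to 0.119. The Nr1d1 call (adjusted p = 0.0457) was lost without male control pups replicate 2, 4 or 5, any 1 of the 5 male PBDE pups, adult controls replicate 1, 2 or 4 or adult PBDE rats replicate 3, 4 or 5 (0.0582 to 0.0988). It was lost too with the compared groups alone (0.108), a trended, robust eBayes (0.0731) and no shrinkage (0.085), within a range of 0.00818 to 0.108.

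None of the 16 lists past the threshold for age by dose held with an estimated correlation. Cholesterol synthesis had a higher effect in adults for 4 of 18 members, 13 when adjusted over the list alone, with Lss at log2 1.43 ± 0.28 (adjusted p = 1.47e-13, and 0.145 with an estimated correlation). Fatty acid and triglyceride genes had a higher effect for 5 of 19, with Fasn at 1.98 ± 0.38, and a lower one for 1; adjusted over the list alone, these were 10 and 1 (adjusted p = 2.95e-06, and 0.145 with an estimated correlation). Male-biased genes had a lower effect for 4 of 11, 5 when adjusted over the list alone, with Cyp2c11 at -2.50 ± 0.45 (adjusted p = 4.23e-06, and 0.0867 with an estimated correlation). Cyp2c11 too lay near the top of the scale in adult PBDE rats (mean 14.2). The other 13 were cell cycle, NRF2, endothelial, p53, interferon, gluconeogenesis, glutathione, amino acid, female-biased, bile acid, CAR and PXR, lymphocyte, and glucuronosyl- and sulfotransferase lists, with adjusted p from 7.78e-06 to 0.0443, and from 0.0947 to 0.373 with an estimated correlation. Leaving out 1 array ended 4 of the 16 calls, those of the amino acid, CAR and PXR, lymphocyte and glucuronosyl- and sulfotransferase lists. The 18 other lists had adjusted p from 0.0615 to 0.982, and median, mean and test differed in sign for 6 of them, the AhR, thyroid, PPARalpha, endoplasmic reticulum stress, acute phase and stellate cell lists.

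For age by dose, 579 probe sets passed the false discovery rate of 0.05, 258 with a higher and 321 with a lower effect in adults. The balance moved with the scaling of the arrays, to 219 and 389 with arrays centred on their medians and to 300 and 305 with renewed quantile normalization. By gene the numbers were 160 and 192. The count was 365 without male control pups replicate 5, 376 without male PBDE pups replicate 4 and 373 without adult PBDE rats replicate 4.

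Between male and female control pups, few genes differed. Xist, the X-inactivation transcript, was lower in males (log2 -8.72 ± 0.16, n = 5 per sex, adjusted p = 1.61e-26), and the Y-linked Eif2s3y was higher (5.99 ± 0.10, adjusted p = 1.34e-27). The X-linked Eif2s3 was lower (-0.50 ± 0.08, adjusted p = 0.00449), as was the probe set annotated to Uty (-0.85 ± 0.10, adjusted p = 8.97e-06), a gene known as Y-linked. Xist in males (mean 3.27) and Eif2s3y in females (3.67) lay below the array medians, so these differences may be too small. The direction for Uty is against a Y-linked gene, and the second Uty probe set did not differ (-0.11, adjusted p = 0.836); whether the first reads another transcript was not tested. Ifrd1 was higher in males (1.25 ± 0.18) and Akr1b7 lower (-1.88 ± 0.30, adjusted p = 0.00305), while Kdm5c did not pass (-0.35 ± 0.17, adjusted p = 0.599). In all, 11 probe sets passed at 0.01, 2 higher and 9 lower, and all 6 genes among them had arrays apart. Of all 14217 genes, 220 had arrays apart, where chance gives 0.794%. The Eif2s3 call was lost without male control pups replicate 2, 3 or 5 or female control pups replicate 2, 4 or 5 (0.0106 to 0.0298) and with the compared groups alone (0.0371; range 8.42e-04 to 0.0371). The Akr1b7 call was lost without male control pups replicate 3 or 4 or female control pups replicate 2 (0.0149 to 0.0206), with the compared groups alone (0.12), the 15 arrays of the batch (0.0528) a trended, robust eBayes (0.0103) and no shrinkage (0.0203), over a range of 8.86e-04 to 0.12.

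Of the lists, female-biased adult genes were lower in male control pups, with 2 of 9 lower when adjusted over the list alone, and Cux2 (log2 -1.50 ± 0.31, adjusted p = 0.0414) and Cyp2c7 (-1.45 ± 0.29, adjusted p = 0.0382) not past over all probe sets (list adjusted p = 9.57e-05, and 0.00427 with an estimated correlation). With fry's mixed test this call was lost (0.171; range 2.3e-05 to 0.171). Sex-chromosome genes, 3 of 5 lower, Uty among them, and 1 higher by either count, held at both correlations (2.73e-05, and adjusted p = 0.0117 with an estimated correlation). Cell cycle genes were higher as a list at 4.83e-14 (adjusted p = 0.142 with an estimated correlation), with 3 of 28 higher when adjusted over the list alone and Ccna2 at 1.06 ± 0.28 (adjusted p = 0.17). Acute phase, amino acid, fatty acid, neutrophil, PPARalpha, gluconeogenesis, growth hormone and lymphocyte lists passed at 4.18e-05 to 0.0495, and stood at adjusted p from 0.142 to 0.718 with an estimated correlation. Leaving out 1 array ended 6 of these 11 list calls. The other 23 lists had adjusted p from 0.105 to 0.923, and median, mean and test differed in sign for the AhR, bile acid, endoplasmic reticulum stress, interferon, hepatocyte and cholangiocyte lists.

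Male and female PBDE pups lay in different array batches. Xist (log2 -8.17 ± 0.16), Eif2s3y (6.12 ± 0.10), Uty (-0.97 ± 0.10) and Eif2s3 (-0.50 ± 0.08, adjusted p = 0.0034) passed, and Kdm5c did not (-0.30 ± 0.17). The second Uty probe set stood at 0.04 (adjusted p = 1). Xist in males (mean 3.23) and Eif2s3y (3.48), Cyp2c13 (5.09) and Cyp2a2 (5.10) in females lay below the array medians. Cyp2c13 was higher in males (4.13 ± 0.48, adjusted p = 5.69e-06), as were Sult1e1 (2.54 ± 0.35, adjusted p = 1.97e-04) and Cyp2a2 (0.93 ± 0.16, adjusted p = 0.00845), and Pbdc1 was lower (-0.50 ± 0.08, adjusted p = 0.00308). Male-biased adult genes were higher in males, 3 of 11 and 7 when adjusted over the list alone (adjusted p = 1.38e-20, and 4.2e-05 with an estimated correlation), with Cyp2c11 at 1.69 ± 0.32 (adjusted p = 0.0258) and Hsd3b5 at 1.01 ± 0.21 (adjusted p = 0.0866), or 0.66 without male PBDE pups replicate 1 (0.0109; range 0.0109 to 0.647). Cyp2c11 passed without male PBDE pups replicate 3 (0.00227) or female PBDE pups replicate 4 (0.00622; range 0.00227 to 0.237). Sex-chromosome genes, 3 of 5 lower and 1 higher by either count, passed at 7.48e-07 (adjusted p = 0.00337 with an estimated correlation) and did not pass fry's directional test (0.326; range 3.14e-07 to 0.326). Cell cycle, Kupffer cell, AhR, fetal, interferon, lymphocyte, endothelial and CAR and PXR lists passed at 1.64e-18 to 0.0388, and stood at adjusted p from 0.0683 to 0.647 with an estimated correlation; leaving out 1 array ended 6 of the 10 list calls. The other 24 lists had adjusted p from 0.0609 to 0.988, and median, mean and test differed in sign for the glutathione, PPARalpha, growth hormone, clock, hepatocyte, stellate cell and adipose lists. The total was 14 probe sets, 5 higher and 9 lower, and 7 of 8 genes had arrays apart. Of all 14217 genes, 151 had arrays apart, where chance gives 0.794%. For Cyp2c13, Sult1e1, Cyp2a2, Pbdc1 and the male-biased list, none of which passed between control pups, batch and sex cannot be told apart.

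Of these genes, Cyp2c13 (adjusted p = 0.0404; range 1.93e-07 to 0.0404), Sult1e1 (0.101; range 3.27e-07 to 0.101), Cyp2a2 (0.144; range 7.6e-04 to 0.144), Eif2s3 (0.0245; range 0.00136 to 0.0245) and Pbdc1 (0.0404; range 8.89e-04 to 0.0404) did not pass with the compared groups alone. The Eif2s3 call was also lost without male PBDE pups replicate 1 or 4 or female PBDE pups replicate 1, 2, 3 or 4 (0.01 to 0.0211). That of Cyp2a2 was lost without any 1 of the male PBDE pups or female PBDE pups replicates 1 to 4 (0.0104 to 0.0608), with a replicate block (0.0163), no shrinkage (0.038), the 3' minus 5' covariate (0.0126) and without the 2 arrays least like their groups (0.0134). That of Pbdc1 was lost without male PBDE pups replicate 2 or 4 or female PBDE pups replicate 2 or 4 (0.0128 to 0.0185) and with a replicate block (0.0102).

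The sex-by-dose test compared the dose effect in females with that in males, where array batch and the interaction cannot be told apart. By limma 0 probe sets passed at 0.01, and 1576 had an unadjusted p under 0.05. Without male control pups replicate 2, or without male PBDE pups replicate 3, 1 probe set passed. The second was that of Cyp2c13, whose effect was lower in females (log2 -3.68 ± 0.67, adjusted p = 0.12) and passed at -4.14 (0.00738; range 0.00738 to 0.641). Sult1e1 (-1.78 ± 0.50, adjusted p = 0.741), Cyp2c11 (-1.51 ± 0.45, adjusted p = 0.761) and Hsd3b5 (-1.10 ± 0.30, adjusted p = 0.717) did not pass, nor did Xist (-0.56 ± 0.22) or Eif2s3y (-0.13 ± 0.14). Male-biased adult genes had a lower effect in females as a list, 4 of 11 when adjusted over the list alone (adjusted p = 9.19e-08, and 0.0207 with an estimated correlation). With fry's mixed test this call was lost (0.361; range 2.22e-10 to 0.361). The other 12 lists past the threshold stood at 2.8e-06 to 0.0434, and at adjusted p from 0.113 to 0.761 with an estimated correlation. They were acute phase, fatty acid, amino acid, CAR and PXR, erythroid, neutrophil, female-biased, endothelial, AhR, PPARalpha, fetal and interferon lists, and leaving out 1 array ended 7 of the 13 calls. The other 21 lists had adjusted p from 0.0781 to 0.978, and median, mean and test differed in sign for the NRF2, thyroid, p53, endoplasmic reticulum stress, lymphocyte, cholangiocyte and adipose lists.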

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

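The tests of array batch, of a shift towards adult expression and of adult RNA in pup samples were chosen after the results were seen; the RNA integrity covariate was added after seeing the data, with its prediction written before its result.

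In each group of 5 arrays, a value was singled out when its gap to the nearest other array was more than 0.71 of the group's range. Of 456 groups of values tested, 34 (7.46%) met this, where chance gives about 1 in 20 groups, or 22.8. The arrays met most often were female control pups replicate 4 (5 values), adult male PBDE rats replicate 5 (3) and male control pups replicate 3 (3). On adult male PBDE rats replicate 5 the 3' minus 5' difference stood apart for Gapdh (gap ratio 0.792; 2.25 against 0.73 to 1.04 on the other 4) and for Actb (0.775). Hybridisation spikes stood apart on male PBDE pups replicate 4 (0.725).

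Among male pups, single arrays stood apart for these genes, with the gap ratio in brackets: Por (0.731), Cyp2c13 (0.819) and Fads2 (0.789) on control replicate 3, Cyp2a3 (0.749) and Cltrn (0.807) on control replicate 4, Dio1 (0.806) on PBDE replicate 1, Sult1e1 (0.851) on PBDE replicate 2, Snx10 (0.74) on PBDE replicate 3, Sult1b1 (0.784) on PBDE replicate 4 and Ahr (0.791) on PBDE replicate 5. Among female pups these were Cyp1a1 (0.829) and Xist (0.74) on control replicate 1, Ahsp (0.838) on control replicate 3, Nqo1 (0.836), Ttr (0.818), A2m (0.799), Fgl1 (0.743) and Gsta4 (0.756) on control replicate 4, Cxcl9 (0.728) and Fcgr2b (0.775) on control replicate 5, Ugt2b (0.801) on PBDE replicate 2 and Ahr (0.892) on PBDE replicate 5. Among adults these were Cyp1a2 (0.813) and Abcc3 (0.842) on control replicate 3, Ahr (0.756) on control replicate 4, Sema3c (0.892) and Ccdc126 (0.75) on control replicate 5, Zfp189 (0.806) on PBDE replicate 2, Gstm3 (0.744) and Ugt2b (0.973) on PBDE replicate 4 and Cyp1a2 (0.728) on PBDE replicate 5.

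The dose effect differed between adult and pup males by the interaction test for 44 of the genes named in the report. Effects are signed, PBDE minus control, so a higher adult effect can be a weaker fall than in pups, or none. H19, for one, fell in male pups and ran from 6.53 to 7.23 over the adult arrays of both groups. The effect was higher in adults (log2) for H19 (3.97), Nfe2 (2.72), Asns (2.59), Qsox1 (2.23), Aacs (2.16), Noct (2.16), Abcc3 (2.11), G0s2 (2.11), Cyp17a1 (2.08), Nr1d1 (2.06), Elovl6 (2.06), Igfbp2 (2.04), Fgf21 (2.02), Abcg8 (2.01), Qpct (1.98), Fasn (1.98), Cyp8b1 (1.88), Ppp2r2b (1.83), Lss (1.43), Hsd17b7 (1.39), Fads2 (1.23), Agxt (0.74), Fcgr2b (0.64) and Nr1i2 (0.54). It was lower in adults for Rup2 (-7.79), Sult1e1 (-5.41), Cyp2a3 (-5.19), Cltrn (-4.91), Cyp2c13 (-4.45), Cyp2c7 (-4.40), Cxcl9 (-2.80), Socs2 (-2.70), Ttc39a (-2.66), Hao2 (-2.64), Fbxl17l1 (-2.53), Cyp2c11 (-2.50), Sult1b1 (-1.97), Cyp2c12 (-1.74), Hhex (-1.56), Zdhhc2 (-1.50), Gstm2 (-1.50), Ccdc126 (-1.14), Ccnb1 (-1.12) and Gsta4 (-0.70). Rup2, Sult1e1, Cyp2c13, Cyp2c7 and Cyp2c11 lay near the top of the scale in adults, so their differences may be too large. The pup rises of Rup2, Cyp2c13 and Cyp2c7 may in turn be too small, so the direction of the bias is open for them. Nfe2, Asns, Noct, Abcc3 and Nr1d1 lay below the array medians in adult controls, and Cyp2a3 and Cltrn did in both adult groups. So did Abcg8, Ppp2r2b and Qpct in male PBDE pups, Fbxl17l1 in adult PBDE rats and Hao2 in male control pups. The differences of all these genes have no exact size. Between the sexes of pups, the dose effect on the list of male-biased adult genes differed (adjusted p = 0.0207 with an estimated correlation), a call lost with fry's mixed test (0.361; range 2.22e-10 to 0.361). Age and sex of the animals, as the design names them, stay open as explanations of these differences. Adults were also dosed after weaning, so age and length of dosing cannot be told apart. For the list that differed between the sexes, array batch and the interaction cannot be told apart, since female PBDE pups alone among pups lay in the second batch.

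The Gapdh and Actb 3' minus 5' differences did not pass after adjustment over 20 tests, where a smallest possible p of 0.00794 left little room to pass. Their mean was higher in PBDE than in control groups (exact permutation p = 0.254 in male pups, 0.0397 in female pups and 0.0238 in adults, not adjusted). This mean difference was the reason to weigh lower RNA integrity as the source of the dose calls. With this difference as a covariate, the log2 change of the called probe sets had a median ratio to that without it of 0.996 (quartiles 0.940 and 1.05) in male pups, 0.951 (0.859 and 1.04) in female pups and 0.948 (0.845 and 1.03) in adults. Of the calls, 1424 of 1654, 841 of 1315 and 556 of 924 were shared with the covariate fit, which argues against RNA integrity as the whole source. A smaller part for single genes stays open, since 1751 probe sets followed the covariate itself.

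In female pups, array batch was weighed against dose. Over the 1315 female calls, the log2 change in male pups, measured within 1 batch, was a median of 0.855 of the female change (quartiles 0.645 and 1.06), which argues against batch as the source of most of these calls. Between the sexes, 0.580 times as many probe sets had an unadjusted p under 0.05 across batches as within 1 batch, which argues against a broad batch shift. Of the genes that differed between male and female PBDE pups, Xist (log2 -8.17), Eif2s3y (6.12), Uty (-0.97) and Eif2s3 (-0.50) differed about as much between control pups within 1 batch (-8.72, 5.99, -0.85 and -0.50), which argues against batch for them. For Cyp2c13, Sult1e1, Cyp2a2, Pbdc1 and the male-biased list, batch and sex cannot be told apart.

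Several genes high in adult livers rose in male PBDE pups, among them Rup2, Sult1e1, Cyp2c13 and Cyp2c7. Others bright in adult controls hardly moved between male control and male PBDE pups, such as Obp3 (3.97 and 4.01, adults 13.7) and Stac3 (5.98 and 5.84, adults 12.4). A hypothesis is that livers of male PBDE pups had shifted earlier towards adult expression for part of the genes. Of 517 probe sets called in male pups and between adult and female pup controls, 83.0% moved towards the adult level. Among probe sets not called in male pups the share was 63.5%, already above the 60% set as the bound, so the test was weak. The adult and female pup controls also differ in sex and array batch, so the test does not read age alone. Over all 31042 probe sets the male pup change correlated with their difference at Pearson's r = 0.255 and Spearman's rho = 0.162. Adult liver RNA in the pup samples was set against this hypothesis. The adult share that Rup2 would need was 23.2%. With it, 10 probe sets bright in adults and dim in pups stayed a median of 4.97 (log2, quartiles 3.64 and 5.39) below the level expected. That argues against adult RNA at this share. Rup2 lay near the top of the scale in adults, so this share may be too high and the shortfall too large, and a smaller share of adult RNA stays open. Cyp2a3 and Cltrn rose too and were low in adults, and PBDE itself acting on these genes stays open.

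The number of calls was compared with 100 splits of the same arrays, the real one included. No other split gave as many calls for male pups (1654 probe sets, highest other 13), female pups (1315, 5), control pups by sex (11, 2), PBDE pups by sex (14, 6) or age by dose (579, 186). These counts argue against chance but do not exclude it, since 100 splits cannot show a share under 1 in 100. Splits that mix the groups also carry the real difference in their spread, which lowers their counts. For age by dose, the other split of the adult arrays given below is a further limit. For sex by dose the count was 0 (by limma, with 1576 at an unadjusted p under 0.05), so all 100 splits gave as many by construction, the highest other gave 0, and this comparison says nothing about chance. In adults (924) 2 splits were as large, the real one included, and the highest other gave 1355, so the count alone does not tie these calls to dose. The other split set control replicates 1 and 5 with PBDE replicates 3, 4 and 5 against the others, and it points to a structure of the adult samples other than dose; both groups lay in 1 array batch, so batch as labelled did not make it.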

How the results depend on the processing

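The 3' minus 5' covariate and leaving out the 2 arrays least like their groups were tests chosen after the data were seen.

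Of the named results, 45 genes were called in male pups and 41 kept their call under all alternatives run; the numbers were 39 and 34 in female pups, 39 and 29 in adults, 6 and 4 by sex in controls, 8 and 3 by sex in PBDE pups, and 23 and 18 for age by dose. None reversed its direction. Of the list calls, 6 of 15 in male pups, 5 of 16 in female pups, 1 of 9 in adults, 1 of 11 by sex in controls, 1 of 10 by sex in PBDE pups, 0 of 13 for sex by dose and 0 of 16 for age by dose were kept.

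The number of probe sets past the threshold changed with the false discovery rate by construction: 3304 in male pups and 2565 in female pups at 0.05, 360 in adults and 161 for age by dose at 0.01, and 35 by sex in controls at 0.05. Asking for a 1.5-fold change also lowered it by construction, to 767, 636 and 324 in male pups, female pups and adults. With only the compared groups fitted, adults had 269 and PBDE pups by sex 8. This fit has fewer arrays for the spread, yet male pups kept 1184 and female pups 968. Fewer arrays alone may therefore not account for the adult drop, whose cause was not tested. The main fit shares 1 spread per probe set over all 6 groups. The mean correlation of arrays within a group was 0.9915 in adult controls and 0.9902 in adult PBDE rats. In the pup groups it ran from 0.9924 to 0.9933. The shared spread may therefore be too small for adults. PBDE pups by sex had 8 with 1 probe set per gene, by construction. Adults had 535 with the 15 arrays of the batch and 494 without the 2 least-alike arrays; the cause was not tested. Spearman's rho between male and female pups was 0.721 with the filter on low values, which keeps fewer probe sets. With a replicate block the counts were 1603, 1266 and 961 in male pups, female pups and adults.

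Leaving out 1 array, the counts ran from 1194 to 1492 in male pups, 880 to 1192 in female pups, 597 (without adult PBDE replicate 4) to 1032 in adults, 10 to 16 by sex in controls and 11 to 14 in PBDE pups. For sex by dose they ran from 0 to 1 (without male control pups replicate 2, or male PBDE pups replicate 3), where limma gave 0 and 1576 at an unadjusted p under 0.05. For age by dose they ran from 365 (without male control pups replicate 5) to 703, with 376 without male PBDE pups replicate 4 and 373 without adult PBDE replicate 4. Beyond the smaller number of arrays, the cause was not tested. The number of arrays limits precision.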

Other observations

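No tests here were chosen for these values, which were noticed after the data were seen.

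Ugt2b, a glucuronosyltransferase gene with 2 probe sets (correlation 0.928), lay at 8 or higher on 0 of 5 male control pups, 3 of 5 male PBDE pups, 0 of 5 female control pups and 4 of 5 female PBDE pups. Among adults it did so on 2 of 5 controls and 4 of 5 PBDE rats, and its values ran from 4.95 to 13.7 and from 5.61 to 13.4. Its dose effect did not pass in male pups (log2 4.16 ± 1.72, adjusted p = 0.127), female pups (2.45 ± 1.72, adjusted p = 0.468) or adults (3.21 ± 1.72, adjusted p = 0.361). Single arrays moved it: in male pups it was 3.35 without PBDE replicate 1 and 5.24 without PBDE replicate 3. In female pups it was 3.45 without PBDE replicate 2. In adults it was 2.31 without control replicate 5 and 4.75 without PBDE replicate 4.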
